A study of Mus musculus with 8 samples.

How the data were processed

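RNA was taken from whole testes of C57BL/6 males, WT or KO for Dnmt3a, at 19 and 25 dpp, with 2 libraries per group and 8 libraries in all. Per the labels, RNA was extracted with Trizol, treated with DNase and made into stranded mRNA libraries. Per the deposited processing notes, the authors aligned reads to mm10 with STAR 2.7.0a and counted them with featureCounts 1.5.1. The deposited values are raw counts, 1 file per library. The strand setting of the counting, the handling of reads that align to several places and the gene annotation are not stated. Each file held 55292 entries, of which 54087 were genes and 1205 were repeat families. The repeat families were kept out of the gene totals and gene tests and were tested apart with the library sizes and scaling factors of the genes. Gene totals were 27142989 and 31793256 in WT and 22515812 and 33192200 in KO at 19 dpp. They were 50445334 and 40972444 in WT and 33864327 and 26405372 in KO at 25 dpp. A floor of 3 counts, between 0.0812 and 0.126 CPM per library, covers counting error only. It was used in list medians given with genes at their bound, where a group without counts got 3 counts over its summed library size. Genes without counts in both groups were left out there, and the floor entered neither the fits nor the CPM values.

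Genes were placed on GENCODE M21 (GRCm38, the same assembly as mm10) by symbol, for 28418 entries, or by synonym, for 245. Another 81 symbols belonged to several genes and 25343 entries, mostly clone names, had no match. Coordinates are 1-based. Of the 105 genes named, 14 overlap another protein-coding gene, and Izumo1 and Pcolce do so on the same strand, with Rasip1 and Fbxo24.

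Counts were scaled by TMM, filtered with filterByExpr by group, which left 23353 genes, and fitted in edgeR 4.0.16 with robust quasi-likelihood and 1 mean per group, leaving 4 residual degrees of freedom. The 5 contrasts were tested with Benjamini-Hochberg adjustment at 0.05: KO against WT at each age, 25 against 19 dpp in each genotype, and the difference between the KO effects at the 2 ages. The SE is the absolute log2 fold change over the square root of F. R 4.3.3 was used. Gene lists, 20 in number and fixed before the data were examined, were tested in the 5 contrasts with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated, where no list was called. Chromosomes were tested in the same way as 21 lists. List members Shoc1, Majin, Terb2, Dnmt3c and Rtl1 had no matching entry. The lists were undifferentiated and differentiating spermatogonia, early meiotic prophase, pachytene to secondary spermatocytes, round and elongating spermatids, Sertoli, Leydig, peritubular myoid, interstitial stromal and endothelial cells, macrophages, red blood cells, epididymis, DNA methylation machinery, piRNA pathway, imprinted genes, p53 targets and apoptosis, steroid and cholesterol synthesis, and cell cycle.

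Genes to name were set by a rule written before the data were examined. Per contrast it took Dnmt3a, the 6 largest changes in each direction past the threshold, and up to 4 members per list, 2 by p and 2 by expression. The largest changes needed at least 8 CPM in the higher group and at least 10 summed counts in the lower group. Gm, Rik, LOC and mt- names were barred. Every library of the higher group had to lie above every library of the lower one, except for the difference between the ages. Genes without counts in the lower group, such as 176 in KO at 25 dpp, could not be among them. The rule gave 421 pairs of gene and contrast over 181 genes. For the 5 contrasts the text names 135 pairs over 92 genes. That reduction was made after the values were seen, except that the 12 largest changes of KO against WT at each age are all named. Another 13 genes, named only in the closing parts, were chosen after their values were seen.

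Alternatives tried were DESeq2 size factors, total counts or the sum of Sertoli markers as scaling, no filter or at least 5 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, glmTreat against 2-fold, leaving out mitochondrial genes, a replicate block, only the libraries of the groups compared, fry, and leaving out each library in turn. With 1 library left out its group has a lone library, which is assumed to vary like the others, and 3 residual degrees of freedom remain. The genes called with all libraries were selected on the libraries that remain. That they keep their sign is thus close to fixed in advance and is no separate support. The procedure was tested on simulated data made from the real libraries, with 200 genes changed. At 19 dpp 25% of 2-fold and 82% of 4-fold changes were called, and 6.96% of calls were false. At 25 dpp 1% of 2-fold and 55% of 4-fold changes were called, and 9.68% of calls were false. The real contrasts of KO against WT called far more genes, 5145 and 14840, where the Benjamini-Hochberg cutoff is less strict. The simulated shares therefore do not carry over to them. The bounds for the tests of swapped labels, sequencing depth and the Sertoli share were written before their values were seen. Further conditions, which leave the tests of swapped labels (stromal genes), germ cell delay, the Sertoli share and L1Md families undecided, were added after.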

Results

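RNA was measured in whole testes of C57BL/6 male mice that were wildtype (WT) or homozygous mutant (KO) for Dnmt3a, the gene of a DNA methyltransferase that sets new methylation marks in the germ line. Testes were taken at 19 or 25 days post partum (dpp), ages at which the first wave of germ cells passes through meiosis and then forms haploid spermatids. There were 4 groups of 2 libraries each, 8 libraries in all. The total counts were 28725404 and 33618702 in the WT libraries and 23870641 and 35013859 in the KO libraries at 19 dpp. At 25 dpp they were 52601321 and 42808119 in WT and 35840994 and 27881556 in KO. Levels below are CPM (counts scaled to a common library size), given as mean ± SD with n = 2. Fold changes are log2 values of KO over WT, or of 25 over 19 dpp, with the standard error (SE) of the edgeR quasi-likelihood fit. Adjusted p-values of genes come from that test with Benjamini-Hochberg adjustment over 23353 genes, and those of gene lists from camera with a preset correlation between genes.

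Dnmt3a itself (chromosome 12, 3806007 to 3914443, mm10) stood at 147 and 141 CPM in the WT libraries at 19 dpp and at 114 and 112 CPM in KO. At 25 dpp it stood at 48.7 and 70.0 CPM in WT and at 76.9 and 67.2 CPM in KO. The KO over WT difference was −0.35 (SE 0.178, adjusted p = 0.201) at 19 dpp and 0.28 (SE 0.179, adjusted p = 0.204) at 25 dpp. With libraries scaled to Sertoli markers the second value was −1.11 (edgeR adjusted p = 8.37e-04). The labels do not say which part of the gene was deleted, and counts over the whole gene include reads from exons that a deletion leaves in place. The count of Dnmt3a is therefore no check of the genotype labels.

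The first comparison asks how the RNA of mutant testis differed from that of wildtype at 19 dpp, and 5145 of 23353 genes changed, 2054 up and 3091 down. With libraries scaled to total counts these were 1285 and 3417, and with libraries scaled to Sertoli markers 83 and 9838. Meiotic genes were lower and genes of Sertoli cells, the supporting cells of the seminiferous tubule, were higher in both KO libraries. Of 32 early meiotic prophase genes 27 fell (30 adjusted over the list alone), with a median of −1.89. Adjusted p was 9.14e-22 by camera, and adjusted p = 0.455 with an estimated correlation. Spo11, whose product makes the DNA breaks of meiotic recombination, fell from 51.1 ± 15.0 to 5.99 ± 2.66 CPM (−3.08, SE 0.333, adjusted p = 0.00714). Sycp2, of the synaptonemal complex, fell from 488 ± 138 to 93.5 ± 33.5 CPM (−2.38, SE 0.325, adjusted p = 0.00792), and Stag3, a meiotic cohesin, fell by 1.63 on the log2 scale (SE 0.302, adjusted p = 0.0130). Of 24 genes of pachytene to secondary spermatocytes 21 fell (22 adjusted over the list alone), with a median of −3.53. Adjusted p was 5.18e-18 by camera, and adjusted p = 0.455 with an estimated correlation. Among these, the sperm surface gene Adam2 went from 110 ± 58.9 to 1.79 ± 0.687 CPM (−5.91, SE 0.560, adjusted p = 0.00714) and the germ cell lactate dehydrogenase Ldhc from 338 ± 282 to 5.35 ± 1.35 CPM (−5.97, SE 0.835, adjusted p = 0.00825). When replicate 1 of KO at 19 dpp was left out, edgeR called 0 genes (lowest adjusted p = 0.0800, with 5256 genes at an unadjusted p under 0.05), limma-voom called 0 and DESeq2 3743, while all 5145 genes kept their sign. Without replicate 2 of WT at 19 dpp 1958 genes passed, and without replicate 2 of KO at 19 dpp 1647 passed.

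Other germ cell lists at 19 dpp moved less evenly. Of 24 genes of the piRNA pathway, which silences transposons in germ cells, 18 fell (18 adjusted over the list alone), with a median of −1.88. Adjusted p was 4.32e-15 by camera, and adjusted p = 0.455 with an estimated correlation. Ddx4, the germ cell RNA helicase, fell by 2.08 on the log2 scale and Mael by 2.10. Of 30 cell cycle genes 19 fell (22 adjusted over the list alone), with a median of −0.91. Adjusted p was 3.22e-10 by camera, and adjusted p = 0.530 with an estimated correlation. Genes that fell included the cyclin gene Ccnb2 at −2.06, Top2a at −1.38 and the proliferation marker Mki67 at −1.01. Of 15 genes of differentiating spermatogonia 4 fell (8 adjusted over the list alone), with a median of −0.66 (camera adjusted p = 0.0209, and adjusted p = 0.700 with an estimated correlation). Tex101 fell from 477 ± 69.4 to 82.6 ± 45.5 CPM and Stk31 by 1.82 on the log2 scale. Of 22 genes of undifferentiated spermatogonia 3 rose and 1 fell (the same counts adjusted over the list alone), and the list was not called (camera adjusted p = 0.435), while under Sertoli scaling none rose in edgeR and 9 fell. Gfra1, a receptor of spermatogonial stem cells, rose from 7.42 ± 3.46 to 21.2 ± 2.90 CPM (1.52, SE 0.324, adjusted p = 0.0172), Etv5 rose by 0.75 on the log2 scale with a turn to −0.0902 under Sertoli scaling, and Id4 fell by 1.10. Of 30 round spermatid genes 7 fell (7 adjusted over the list alone), with a median of −0.42. Of the 30 genes, 11 lacked counts in a group and 5 in both groups. With the latter left out and the others of the 11 set to their bound, the list median became −0.22. Adjusted p was 0.0415 by camera, and adjusted p = 0.769 with an estimated correlation. The acrosomal genes Dkkl1 and Zpbp were among those that fell, at −5.05 and −2.34. Of 23 elongating spermatid genes 2 fell (1 adjusted over the list alone) and the list was not called (camera adjusted p = 0.486). Leaving out replicate 1 of KO at 19 dpp, no list member passed the edgeR test, where 5256 of all genes had an unadjusted p under 0.05 and DESeq2 called 3743. Without replicate 2 of KO at 19 dpp 9 pachytene genes fell, and without replicate 2 of WT at 19 dpp 10 cell cycle genes fell. The camera call of differentiating spermatogonia ended without replicate 1 of WT or of KO at 19 dpp (adjusted p = 0.152 and 0.0696) or replicate 1 or 2 of WT at 25 dpp (0.109 and 0.107). That of round spermatids ended without replicate 2 of KO at 19 dpp (0.0840) or replicate 1 or 2 of WT at 25 dpp (0.119 and 0.147).

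Genes of somatic cells were higher in KO at 19 dpp relative to the scaled library. Of 30 Sertoli cell genes 21 rose (25 adjusted over the list alone), with a median of 0.88. Adjusted p was 2.80e-12 by camera, and adjusted p = 0.455 with an estimated correlation. Shbg, the androgen-binding protein of Sertoli cells (chromosome 11, 69614804 to 69617905), rose from 87.3 ± 4.26 to 216 ± 17.5 CPM (1.31, SE 0.146, adjusted p = 0.00714), and Clu rose from 2635 ± 590 to 4757 ± 466 CPM (0.85, SE 0.215, adjusted p = 0.0288). Leydig cells make testosterone outside the tubules, and of 19 of their genes 5 rose and 1 fell (the same counts adjusted over the list alone), with a median of 0.82. Adjusted p was 0.00171 by camera, and adjusted p = 0.604 with an estimated correlation. Scarb1, a receptor for cholesterol uptake, rose by 1.32 on the log2 scale, and Gsta2 fell by 1.41, a gene with near-identical paralogs, so that the assignment of its reads is uncertain. Of 12 interstitial stromal genes 6 rose (8 adjusted over the list alone; median 0.74, camera adjusted p = 3.68e-04, and adjusted p = 0.455 with an estimated correlation), among them Pdgfra by 1.01 and the collagen gene Col1a2 by 0.71. Of 13 endothelial genes 4 rose (10 adjusted over the list alone; median 0.87, camera adjusted p = 2.03e-04, and adjusted p = 0.488 with an estimated correlation), among them Cdh5 by 1.18. Of 12 peritubular myoid genes 3 rose (3 adjusted over the list alone; median 0.39, camera adjusted p = 0.0377, and adjusted p = 0.630 with an estimated correlation), among them the myosin kinase gene Mylk by 0.58. For 15 macrophage genes the median was 0.76 (camera adjusted p = 0.0162, and adjusted p = 0.735 with an estimated correlation) with no single member past the edgeR test. The libraries of the groups overlapped in macrophage genes, with geometric means of 6.88 and 14.5 CPM in WT and 19.5 and 13.9 CPM in KO. Their median was 0.30 without replicate 1 of WT and 0.48 without replicate 1 of KO at 19 dpp, where the list was not called (camera adjusted p = 0.308 and 0.0786), and 1.37 without replicate 2 of WT. The Leydig list rests on replicate 1 of WT at 19 dpp, with geometric means of 18.9 and 49.5 CPM in WT and 52.9 and 60.5 CPM in KO. Without that library 3 Leydig genes rose and the list was not called (median 0.54, camera adjusted p = 0.112), while without replicate 2 of WT 10 rose and without replicate 2 of KO 3 rose. The peritubular myoid call ended without replicate 1 or 2 of WT or replicate 1 of KO at 19 dpp (adjusted p = 0.0558, 0.0667 and 0.0579). With libraries scaled to Sertoli markers the median of all genes moved by −0.82, and the medians became −0.05 for Leydig, −0.46 for peritubular myoid, −0.13 for stromal and for macrophage genes and −0.0039 for endothelial genes. Under that scaling none of these genes rose in edgeR, nor did any of the 30 Sertoli genes that define it, while 1 Leydig, 2 peritubular myoid, 1 stromal and 2 Sertoli genes fell. Without replicate 2 of KO at 19 dpp 12 Sertoli genes and 2 stromal genes rose, without replicate 2 of WT at 19 dpp 13 and 3, and without replicate 1 of KO at 19 dpp no somatic list member passed edgeR, with 5256 of all genes at an unadjusted p under 0.05 and 3743 called by DESeq2.

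Imprinted genes, whose parental marks depend on DNA methylation, rose at 19 dpp in 11 of 37 cases (12 rose and 2 fell adjusted over the list alone), with a median of 0.48 that was −0.37 under Sertoli scaling, where 2 rose and 9 fell. Adjusted p was 3.68e-04 by camera, and adjusted p = 0.455 with an estimated correlation. Peg10 rose from 211 ± 17.7 to 452 ± 16.4 CPM (1.10, SE 0.160, adjusted p = 0.00789) and Gnas by 0.83 on the log2 scale, the latter turning to −0.0317 under Sertoli scaling. Of 22 genes of the DNA methylation machinery 3 rose and 2 fell (4 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.954), while under Sertoli scaling 0 rose and 14 fell in edgeR. Uhrf1, which recruits the maintenance methyltransferase, fell by 1.06 and the histone methyltransferase gene Nsd2 by 0.95. Of 24 p53 targets and apoptosis genes 2 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.750), or 0 and 12 in edgeR under Sertoli scaling, with Mdm2 at −0.75. Of 24 steroid and cholesterol synthesis genes 1 rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.347), or 0 and 16 in edgeR under Sertoli scaling, with Sqle, a cholesterol synthesis enzyme, at −1.14. The 6 red blood cell genes (median 1.13, camera adjusted p = 0.218) and 5 epididymis genes (median −0.35, camera adjusted p = 0.756) were not called. The red blood cell median was −0.63 without replicate 1 of KO at 19 dpp, and the list was called as higher without replicate 2 of WT or of KO (camera adjusted p = 0.0148 and 9.39e-05). The 6 largest rises by the naming rule were Gpr182 (3.44), Srrm4 (3.16), Cdh19 (2.61), Plekhb1 (2.61), Tbc1d30 (2.44) and Necab1 (2.44). The 6 largest falls were Mroh2b (−7.00), Qrich2 (−6.97), Adam3 (−6.85), Pgam2 (−6.84), Abcc12 (−6.81) and Tmbim7 (−6.73), all with adjusted p between 0.00714 and 0.0172. The WT replicates were far apart in these falling genes, as in Qrich2 at 58.8 ± 60.1 CPM. Imprinted genes that rose numbered 4 without replicate 2 of KO or of WT at 19 dpp, and without replicate 1 of KO no gene of this paragraph passed edgeR, with 5256 of all genes at an unadjusted p under 0.05 and 3743 called by DESeq2.

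**Figure D1:**
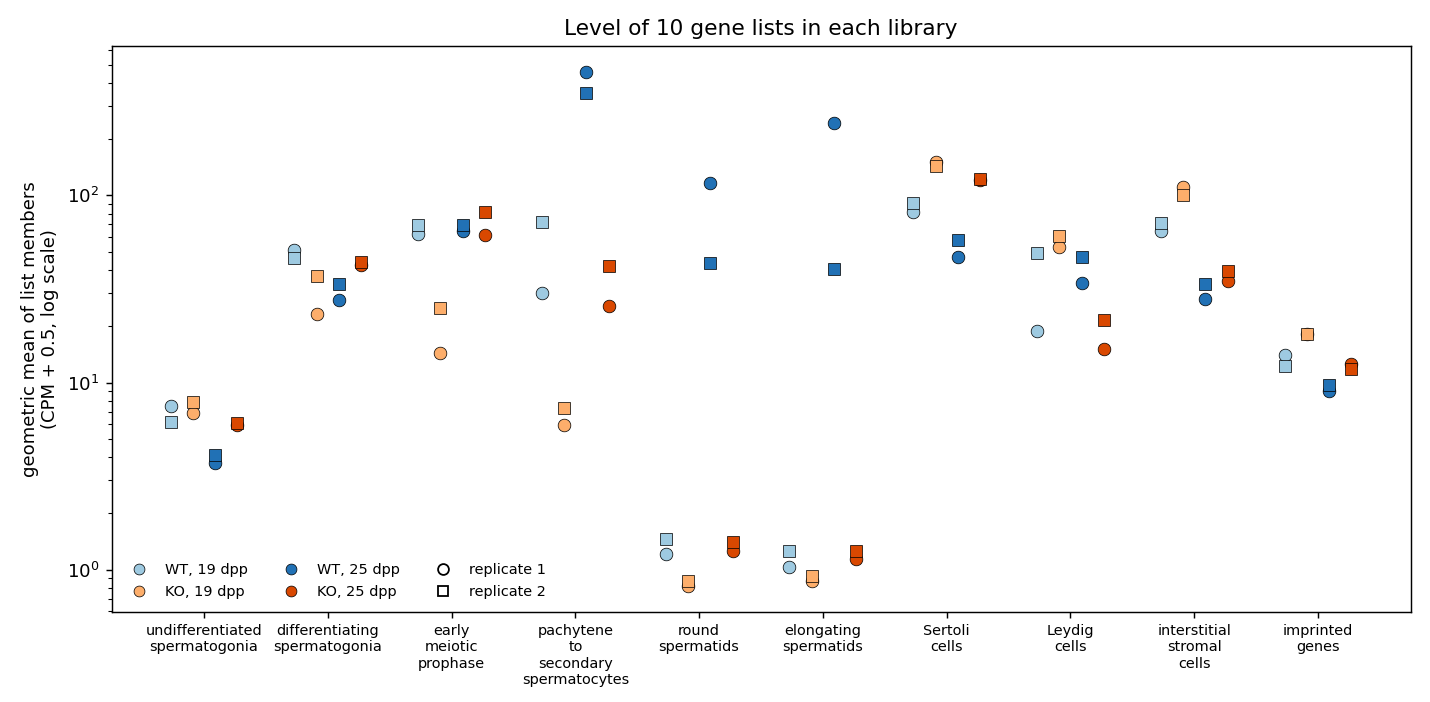
Level of 10 gene lists in each of the 8 libraries, as the geometric mean of the members in CPM plus 0.5 on a log axis, with colour for the group and shape for the replicate. Round spermatid genes stood at 117 and 43.8 CPM in the WT libraries at 25 dpp and between 0.819 and 1.46 CPM in the other 6 libraries.

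The second comparison asks the same at 25 dpp, when haploid spermatids are present in wildtype, and 14840 genes changed, 6096 up and 8744 down. With libraries scaled to total counts the balance turned, to 8991 up and 7108 down, and under Sertoli scaling it was 264 up and 16122 down. Genes of spermatids were far lower in both KO libraries than in WT, with geometric means of 1.25 and 1.40 CPM for round and 1.15 and 1.26 CPM for elongating spermatid genes. In WT these were 117 and 43.8 CPM, and 242.5 and 40.6 CPM. All 30 measured round spermatid genes fell (30 adjusted over the list alone), with a median of −9.30 that became −8.28 with the 3 genes lacking counts in a group set to their bound. Adjusted p was 4.32e-15 by camera, and adjusted p = 0.455 with an estimated correlation. All 23 elongating spermatid genes fell (23 adjusted over the list alone), with a median of −9.32. Adjusted p was 4.77e-08 by camera, and adjusted p = 0.569 with an estimated correlation. The ion channel gene Catsper3 of the sperm tail went from 46.8 ± 30.8 to 0.228 ± 0.0215 CPM (−7.65, SE 0.620, adjusted p = 3.08e-04), and the spermatid kinase gene Tssk1 from 155 ± 99.8 to 1.14 ± 0.108 CPM (−7.08, SE 0.564, adjusted p = 3.15e-04). Values for Tsga8, the tail fibre gene Odf2 and Dkkl1 were −6.68, −3.60 and −4.39, with Odf2 still at 195 ± 0.220 CPM and Dkkl1 at 39.0 ± 17.1 CPM in KO. In the KO libraries 176 genes had no count although WT held at least 8 CPM. All 24 genes of pachytene to secondary spermatocytes fell (24 adjusted over the list alone), with a median of −3.62. Adjusted p was 4.42e-07 by camera, and adjusted p = 0.569 with an estimated correlation. Ccna1, a cyclin of the meiotic divisions, fell from 182 ± 34.4 to 1.64 ± 0.248 CPM (−6.80, SE 0.636, adjusted p = 4.05e-04). Ldhc stood at −4.54 and Tbpl1 at −2.67. The 6 largest falls by the naming rule were Akap4 (−11.02), Spz1 (−10.52), Kif2b (−9.98), Spata20 (−9.93), Pmfbp1 (−9.82) and Nt5c1b (−9.81), with adjusted p between 3.30e-04 and 5.25e-04. The WT replicates at 25 dpp differed in spermatid genes, with Akap4 at 399 ± 359 CPM.

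Earlier germ cell genes were not lower as a group in KO at 25 dpp. Of 22 genes of undifferentiated spermatogonia 11 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.93. Adjusted p was 0.00494 by camera, and adjusted p = 0.569 with an estimated correlation. Ret, the partner of the stem cell receptor Gfra1, rose by 2.17 on the log2 scale (SE 0.307, adjusted p = 9.07e-04) and Foxo1 by 1.09 on the log2 scale, turning to −0.29 under Sertoli scaling. Of 15 genes of differentiating spermatogonia 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.88. Adjusted p was 0.0159 by camera, and adjusted p = 0.699 with an estimated correlation. Stra8, required for entry into meiosis (chromosome 6, 34920163 to 34939344), rose from 33.6 ± 5.86 to 127 ± 12.4 CPM (1.92, SE 0.275, adjusted p = 0.00107), while Dmrtb1 fell by 4.33. Tex101 stood at 505 ± 84.0 CPM in WT and 525 ± 71.5 CPM in KO (0.06, adjusted p = 0.900), which under Sertoli scaling was −1.32 (edgeR adjusted p = 0.0278). Of 32 early meiotic prophase genes 8 rose and 6 fell (8 and 5 adjusted over the list alone), with a median of 0.13 that was −1.23 under Sertoli scaling, and the list was not called (camera adjusted p = 0.170). Prdm9, which marks the sites of recombination, rose from 22.3 ± 2.19 to 94.1 ± 16.3 CPM (2.08, SE 0.228, adjusted p = 4.20e-04), Tex15 rose by 1.26 with a turn to −0.14 under Sertoli scaling, and Stag3 fell by 0.84. Sycp2 stood at −0.56 (adjusted p = 0.154). Scaling to total counts moved the median of all genes by 0.46, the other way from Sertoli scaling. Under Sertoli scaling, which moved the median of all genes by −1.41, the medians of the undifferentiated and differentiating lists were −0.47 and −0.51. There 1 undifferentiated gene rose and 7 fell, and in edgeR 0 rose and 4 fell of the differentiating and 0 and 19 of the early meiotic genes. Differentiating genes that rose numbered 6 without replicate 1 of WT, replicate 1 of KO or replicate 2 of KO at 25 dpp. Early meiotic genes that fell numbered 3 without replicate 1 of WT and 2 without replicate 1 of KO at 25 dpp, and those that rose numbered 5 without replicate 2 of KO. The early meiotic median was −0.10 without replicate 2 of KO and 0.40 without replicate 1 of KO at 25 dpp, where the list was called as higher (camera adjusted p = 0.0252).

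Of 24 piRNA pathway genes 3 rose and 15 fell at 25 dpp (the same counts adjusted over the list alone), with a median of −1.09. Adjusted p was 0.0485 by camera, and adjusted p = 0.762 with an estimated correlation. Pld6 fell from 92.1 ± 3.49 to 20.3 ± 2.38 CPM and Tdrd7 from 509 ± 97.2 to 106 ± 2.06 CPM. Of 30 cell cycle genes 10 rose and 11 fell (the same counts adjusted over the list alone; camera adjusted p = 0.838). The mitotic kinases Plk1 and Aurka fell by 2.87 and 2.98, and Mki67 rose by 0.69 with a turn to −0.70 under Sertoli scaling. Top2a stood at 0.10 (adjusted p = 0.765), or −1.29 under Sertoli scaling (edgeR adjusted p = 0.0176). Of 22 genes of the DNA methylation machinery 10 rose and 6 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0901), with Mbd3 at −1.38. For lists that were not called the balance depended on the scaling. Under Sertoli scaling 0 rose and 14 fell in edgeR for DNA methylation (median −1.11), 0 and 22 for the cell cycle (median −1.51) and 0 and 23 for steroid and cholesterol synthesis (median −1.47). Under total counts these were 15 and 3 (median 0.74), 11 and 7 (median 0.36) and 8 and 7 (median 0.37). Of 37 imprinted genes 19 rose and 5 fell (the same counts adjusted over the list alone), with a median of 0.78 that was −0.61 under Sertoli scaling, where 4 rose and 15 fell. Adjusted p was 0.00361 by camera, and adjusted p = 0.455 with an estimated correlation. Igf2r rose by 1.96 on the log2 scale (SE 0.197, adjusted p = 3.51e-04) and Peg10 by 1.20, which turned to −0.19 under Sertoli scaling. Of 24 p53 targets and apoptosis genes 15 rose and 3 fell (the same counts adjusted over the list alone), with a median of 0.92 that was −0.51 under Sertoli scaling, where 2 rose and 8 fell. Adjusted p was 0.00197 by camera, and adjusted p = 0.455 with an estimated correlation. Sesn1 rose by 1.22, or −0.19 under Sertoli scaling, and Mdm2, whose product degrades p53, fell by 1.02. Of 24 steroid and cholesterol synthesis genes 2 rose and 8 fell (the same counts adjusted over the list alone; camera adjusted p = 0.698), with the squalene synthase gene Fdft1 from 427 ± 123 to 42.2 ± 3.21 CPM and Sqle at −1.79. With replicate 1 of KO at 25 dpp left out, 7 piRNA genes fell, 5 cell cycle genes rose and 3 methylation genes fell. Cell cycle genes that rose numbered 4 without replicate 1 of WT or replicate 2 of KO at 25 dpp. The piRNA call ended without replicate 1 or 2 of WT or replicate 1 of KO at 25 dpp (camera adjusted p = 0.0552, 0.281 and 0.0836), and DNA methylation genes were called as higher without replicate 2 of WT (0.0355).

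Sertoli cell genes were again higher, with 26 of 30 up (27 adjusted over the list alone) and a median of 1.25 (camera adjusted p = 1.48e-10, and adjusted p = 0.455 with an estimated correlation) that was −0.15 under Sertoli scaling. Shbg rose by 1.59 (SE 0.148, adjusted p = 3.17e-04), the tight junction gene Cldn11 by 1.47 and Clu by 1.75 on the log2 scale. Of 19 Leydig genes 6 rose and 5 fell (the same counts adjusted over the list alone), with a median of −0.74 and a test direction of up (camera adjusted p = 0.698). Gstm1 rose by 1.07 and Nr5a1, a regulator of steroid synthesis genes, by 0.82, and both turned under Sertoli scaling, to −0.34 and −0.56. Their group means kept the order of the Sertoli list, lowest in WT at 25 dpp and highest in KO at 19 dpp. Which cells gave the RNA of Gstm1 and Nr5a1 was not tested. Cyp11a1, Cyp17a1 and Hsd3b6 of the Leydig list were lower in KO at 25 dpp. Their means were 0.9249, 1.006 and 4.928 CPM, against 100.7, 81.11 and 84.98 CPM in WT. Of 12 stromal genes 5 rose and 2 fell (the same counts adjusted over the list alone; median 0.25, camera adjusted p = 0.132). Pdgfra and the matrix gene Dcn rose by 1.48 and 1.69, while the collagen gene Col3a1 fell from 238 ± 57.9 to 113 ± 35.4 CPM (−1.07, SE 0.257, adjusted p = 0.00826). Of 12 peritubular myoid genes 3 rose and 1 fell (the same counts adjusted over the list alone), with a median of 0.27, a mean of −0.05 and no call (camera adjusted p = 0.241). Of 13 endothelial genes 2 rose and 1 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.153), and of 15 macrophage genes 1 rose (0 adjusted over the list alone), with a median of 0.02, a mean of −0.08 and no call (camera adjusted p = 0.531). Red blood cell genes (1 of 6 up and 1 down, or 1 and 0 adjusted over the list alone; camera adjusted p = 0.967) and epididymis genes (2 of 5 down, or 2 adjusted over the list alone; camera adjusted p = 0.496) were not called either. Under Sertoli scaling all these somatic lists had negative medians, with 0 up and 15 down in edgeR for Leydig (−2.10), 0 and 7 for stromal (−1.14), 0 and 11 for peritubular myoid (−1.12), 0 and 11 for macrophage (−1.34) and 1 and 9 for endothelial genes (−1.09). Scaling to total counts moved the median of all genes the other way, by 0.46. Of the lists in this paragraph only the epididymis median turned under it, from −0.23 to 0.23. Robo4, an endothelial gene, rose by 3.28. The 6 largest rises by the naming rule were Galnt15 (5.52), Gjc3 (4.57), Hrk (4.51), Atp8b4 (4.41), Ildr2 (4.13) and Igfbp3 (4.11), with adjusted p between 5.37e-04 and 0.00625. Without replicate 1 of KO at 25 dpp no Leydig or stromal gene fell in the edgeR test, and without replicate 2 of WT at 25 dpp 3 Leydig genes fell.

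**Figure D2:**
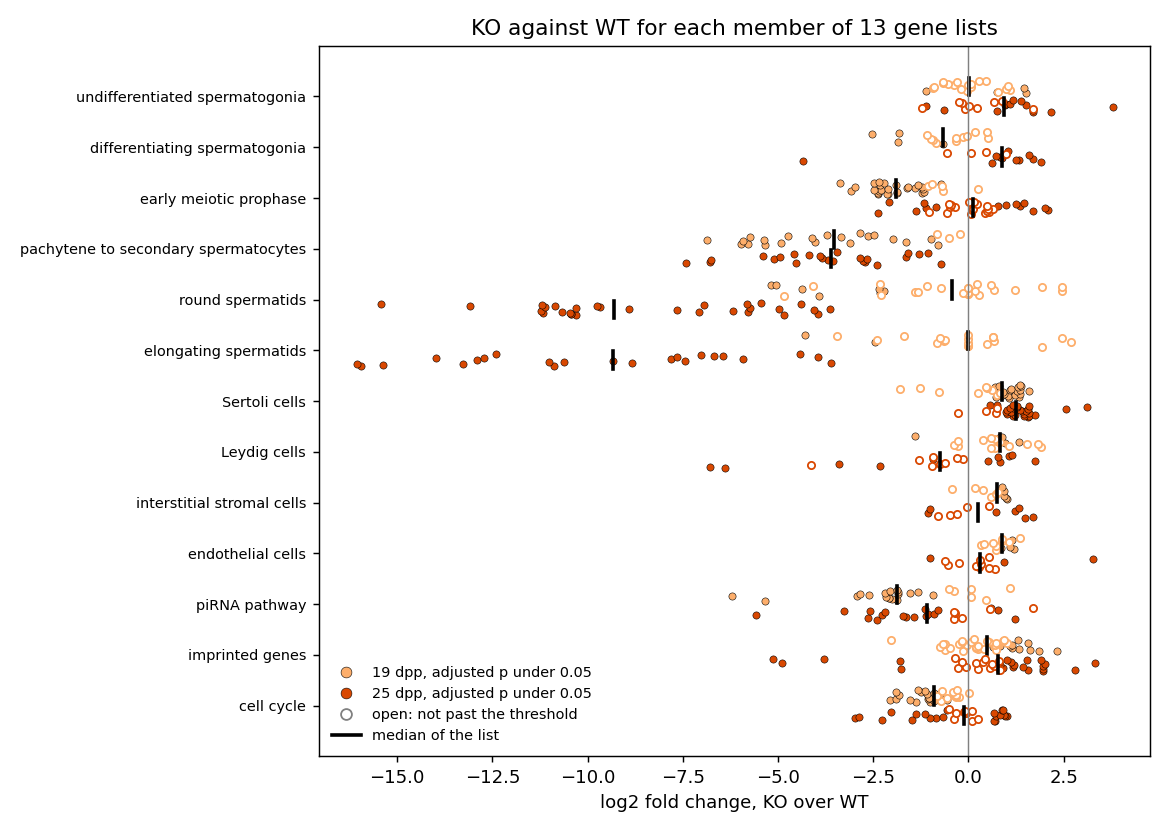
Each point is a member of 1 of 13 gene lists, placed at its log2 fold change of KO over WT at 19 dpp (light) or 25 dpp (dark), filled where the adjusted p was under 0.05, with a bar at the list's median. Early meiotic genes had a median of −1.89 at 19 dpp and of 0.13 at 25 dpp, the latter −1.23 under Sertoli scaling.

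The ages share no library, and of the genes that changed at 19 dpp 1523 rose and 2280 fell at both, where independent lists would share 536.2 and 1157. The calls at both ages come from 1 fit with a shared spread per gene, so they are not independent and this baseline can be too low. Another 105 rose at 19 and fell at 25 dpp and 125 did the reverse, against 769.1 and 806.9 for independent lists. Without replicate 1 of KO at 19 dpp, edgeR called 0 genes at 19 dpp and so none at both ages, with 5256 genes at an unadjusted p under 0.05 at 19 dpp. Genes shared in direction numbered 1183 without replicate 2 of KO and 1513 without replicate 2 of WT at 19 dpp.

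The third comparison gives the change from 19 to 25 dpp in wildtype as a background, with 8151 genes up and 5928 down. Under scaling to total counts the balance turned, to 6297 up and 9716 down, and under Sertoli scaling it was 11707 up and 483 down. All 30 round spermatid genes and all 23 elongating spermatid genes rose (30 and 23 adjusted over the list alone). Camera gave adjusted p = 5.18e-18 and 7.37e-10, and adjusted p = 0.455 and 0.543 with an estimated correlation. Odf1, of the sperm tail, went from 0.181 ± 0.0287 to 194 ± 155 CPM (10.03, SE 0.874, adjusted p = 4.98e-04), Spata20 rose by 10.79 and Tssk1 by 6.84. Of 24 pachytene genes 22 rose (22 adjusted over the list alone; camera adjusted p = 2.27e-06, and adjusted p = 0.569 with an estimated correlation), with Tbpl1 at 2.37, and Syce1 of the early meiotic list rose by 2.25. Genes of undifferentiated (13 of 22) and differentiating spermatogonia (11 of 15), Sertoli cells (23 of 30) and stromal cells (11 of 12) fell (14, 11, 24 and 11 adjusted over the list alone), while 1 undifferentiated and 1 differentiating gene rose. By camera these had adjusted p = 3.62e-04, 0.00197, 1.21e-06 and 2.26e-05, and adjusted p = 0.488, 0.643, 0.455 and 0.455 with an estimated correlation. Among them Foxo1 fell by 1.22, Kit, the receptor of differentiating spermatogonia, by 1.19, Shbg by 1.40 and Col1a2 by 1.51. Prdm9 fell by 1.34 and Dnmt3a by 1.28, and Bcan (−4.29) and Ildr2 (−3.42) were among the 6 largest falls. Peritubular myoid (9 of 12), endothelial (6 of 13), imprinted (24 of 37), p53 target (11 of 24) and DNA methylation genes (11 of 22) fell too (9, 5, 24, 11 and 11 adjusted over the list alone), while 1 peritubular myoid, 6 imprinted, 3 p53 target and 6 DNA methylation genes rose. Their camera adjusted p were 0.00632, 0.0180, 9.75e-04, 0.0139 and 0.0253, with adjusted p = 0.543, 0.623, 0.455, 0.455 and 0.543 with an estimated correlation. Under Sertoli scaling, which moved the median of all genes by 0.87, the medians of peritubular myoid, endothelial, DNA methylation and p53 target genes turned to 0.05, 0.07, 0.49 and 0.20. Most falls ended there, with 6 undifferentiated, 1 differentiating, 1 Sertoli, 2 stromal, 6 imprinted, 1 endothelial and 3 DNA methylation genes still lower. Higher there were 1, 2, 0, 1, 10, 1 and 10 genes of these lists in edgeR, and in peritubular myoid and p53 target lists 1 and 4 genes rose and none fell. Medians and means differed in sign for early meiotic (−0.07 and 0.02), Leydig (−0.23 and 0.13) and cell cycle genes (−0.02 and 0.13), none of them called. Without replicate 1 of WT at 19 dpp Leydig and macrophage genes were called as lower (camera adjusted p = 0.0375 and 0.00504). Without replicate 2 the endothelial call ended (0.0667) and piRNA genes were called as higher (0.0311), and without replicate 1 of WT at 25 dpp the DNA methylation call ended (0.0526).

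The fourth comparison gives the same change in KO, with 2379 genes up and 2072 down. That balance turned in limma-voom (1905 up and 2206 down) and without replicate 1 of KO at 19 dpp (3 and 14), replicate 1 or 2 of WT at 25 dpp (2261 and 2533, 2170 and 2276) or replicate 2 of KO at 25 dpp (223 and 259). Under Sertoli scaling it was 2016 up and 645 down. Of 32 early meiotic genes 29 rose (31 adjusted over the list alone), with a median of 1.99. Adjusted p was 3.42e-27 by camera, and adjusted p = 0.455 with an estimated correlation. Sycp2 rose from 93.5 ± 33.5 to 563 ± 150 CPM and Tex15 by 1.54 on the log2 scale. Of 24 pachytene genes 17 rose (20 adjusted over the list alone; camera adjusted p = 1.94e-14, and adjusted p = 0.455 with an estimated correlation), with Adam2 at 5.02, Ldhc at 4.98 and Crisp2 at 5.60. Of 30 round spermatid genes 6 rose (6 adjusted over the list alone), with a median of 1.36. With the 2 genes lacking counts at both ages left out and those lacking them at 1 age at their bound, the median was 0.72. Adjusted p was 0.00348 by camera, and adjusted p = 0.699 with an estimated correlation. Tex101 rose by 2.67, Ddx4 by 1.84 and Mki67 by 1.22. Of 12 stromal genes 10 fell (10 adjusted over the list alone; camera adjusted p = 3.39e-14, and adjusted p = 0.455 with an estimated correlation), with Col1a1 from 577 ± 63.6 to 67.8 ± 5.52 CPM (−3.09, SE 0.213, adjusted p = 0.00237). Of 19 Leydig genes 7 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 1.40e-05, and adjusted p = 0.543 with an estimated correlation), with Cyp11a1, which starts steroid synthesis from cholesterol, from 58.0 ± 37.3 to 0.925 ± 0.199 CPM (−5.98, SE 1.48, adjusted p = 0.0362). Of 24 piRNA genes 16 rose and of 30 cell cycle genes 14 rose (18 and 16 adjusted over the list alone; camera adjusted p = 8.37e-12 and 2.66e-07, and adjusted p = 0.455 and 0.569 with an estimated correlation). Sertoli (12 of 30 down, 2 up), peritubular myoid (7 of 12 down), endothelial (7 of 13 down), macrophage (5 of 15 down) and imprinted genes (13 of 37 down, 1 up) were called as lower (16, 9, 12, 9 and 13 down adjusted over the list alone). Their camera adjusted p were 2.54e-04, 3.75e-06, 8.68e-07, 9.80e-04 and 1.10e-04, with adjusted p = 0.569, 0.455, 0.455, 0.678 and 0.455 with an estimated correlation. Under Sertoli scaling the falls in edgeR were 4 of Sertoli, 2 of peritubular myoid, 4 of endothelial, 0 of macrophage, 7 of imprinted, 5 of stromal and 2 of Leydig genes. The 6 red blood cell genes had a median of −2.80 (camera adjusted p = 0.0359, and adjusted p = 0.654 with an estimated correlation), with 4 down adjusted over the list alone. Their geometric means were 25.2 and 6.02 CPM at 19 dpp and 3.82 and 3.80 CPM at 25 dpp, and without replicate 1 of KO at 19 dpp the median was −0.89 and the list was not called (camera adjusted p = 0.0822). The call ended too without replicate 1 or 2 of WT at 25 dpp (0.105 and 0.102). Undifferentiated spermatogonia were called as lower without replicate 1 of KO at 19 dpp or replicate 1 or 2 of WT at 25 dpp (0.0131, 0.0334 and 0.0245). Differentiating spermatogonia were called as higher without replicate 2 of KO at 19 dpp (6.56e-05), and epididymis genes without replicate 2 of KO at 25 dpp (7.36e-04). Leydig genes that fell numbered 1 and 2 without replicates 1 and 2 of KO at 25 dpp. Col15a1 fell by 5.12, Cdh5 by 1.83, Shbg by 1.11, the imprinted RNA Rian by 2.31 and Dnmt3a by 0.65. Without replicate 1 of KO at 19 dpp edgeR called 17 genes, limma-voom 58 and DESeq2 3336, while all 4451 kept their sign. Calls numbered 1617 without replicate 2 of KO at 19 dpp, and 1490 and 482 without replicates 1 and 2 of KO at 25 dpp.

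**Figure D3:**
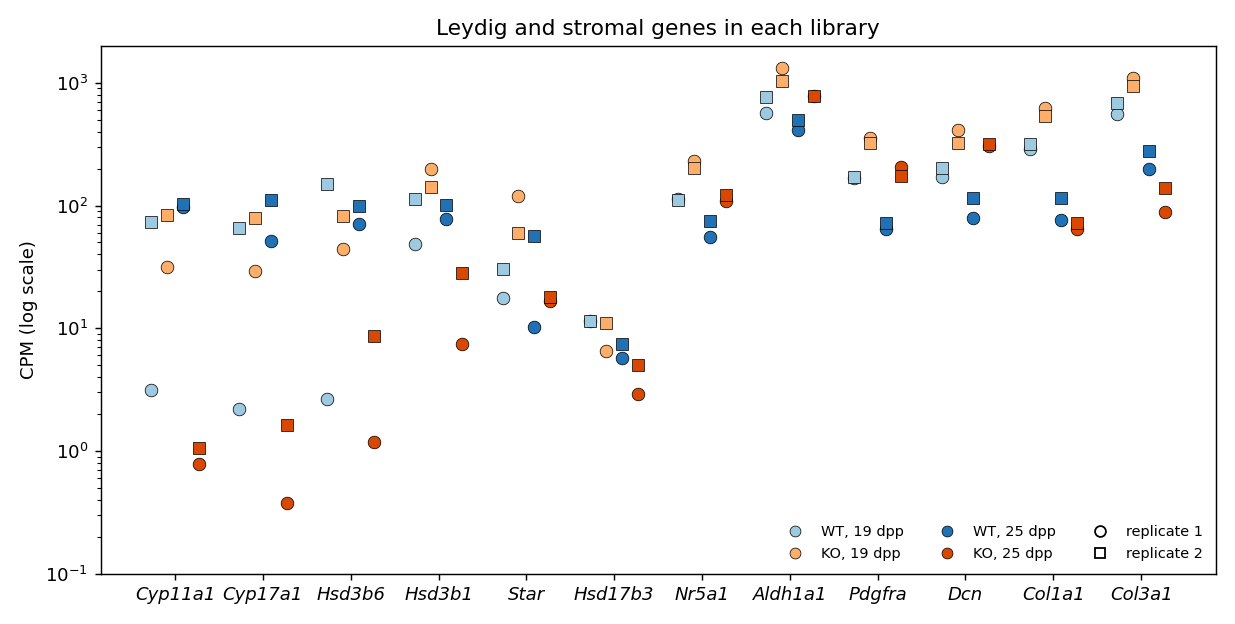
CPM on a log axis of steroid synthesis genes of Leydig cells and of stromal genes in each of the 8 libraries, with colour for the group and shape for the replicate. Cyp11a1 stood at 0.785 and 1.07 CPM in KO at 25 dpp and at 3.15 CPM in replicate 1 of WT at 19 dpp, and between 31.6 and 103 CPM in the other 5 libraries.

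The difference between mutant and wildtype differed with age for 4464 genes, 1793 with a higher and 2671 with a lower log2 difference at 25 than at 19 dpp. Under scaling to total counts this balance turned, to 5548 higher and 1969 lower, while under Sertoli scaling 177 were higher and 2580 lower. Of 32 early meiotic genes 24 had a higher difference at 25 dpp (28 adjusted over the list alone, where 1 had a lower one), with a median of 2.03. Adjusted p was 2.78e-17 by camera, and adjusted p = 0.455 with an estimated correlation. For Stra8 it was higher by 2.76 (SE 0.383, adjusted p = 0.00713), for Prdm9 by 2.75 (SE 0.315, adjusted p = 0.00535), for Tex15 by 1.97, for Tex101 by 2.58 and for Mki67 by 1.71. Spermatid genes went the other way, with Izumo1, the sperm protein that binds the egg, at −6.18 and Odf2 at −2.76. Col1a1 was at −1.41, Fdft1 at −3.11 and Galnt15, among the 6 largest, at 5.24. Differentiating (7 of 15) and undifferentiated spermatogonial (4 of 22), Sertoli (5 of 30), piRNA (6 of 24), p53 target (6 of 24) and cell cycle genes (11 of 30) were called as higher (12, 5, 1, 10, 9 and 13 adjusted over the list alone). A lower difference was found for 2 piRNA, 1 p53 target and 2 cell cycle genes (3, 2 and 3 adjusted over the list alone, and 1 differentiating gene). Their camera adjusted p were 1.36e-05, 0.0159, 0.0180, 0.0161, 0.00197 and 8.25e-04, with adjusted p = 0.543, 0.569, 0.699, 0.735, 0.455 and 0.699 with an estimated correlation; the Sertoli median of 0.48 was −0.06 under Sertoli scaling. There 5 early meiotic genes had a higher difference in edgeR, 2 differentiating, 0 undifferentiated, 1 Sertoli, 0 piRNA, 1 p53 target and 0 cell cycle genes, and 2 piRNA, 1 p53 target and 1 cell cycle genes had a lower one. Scaling to total counts moved the median of all genes the other way, by 0.55. Under it the pachytene, peritubular myoid and stromal medians turned positive, to 0.48, 0.44 and 0.27. Round spermatid (10 of 30), elongating spermatid (8 of 23) and Leydig genes (5 of 19) were called as lower (11, 10 and 7 adjusted over the list alone; camera adjusted p = 1.33e-06, 9.10e-07 and 0.0159, and adjusted p = 0.569, 0.569 and 0.699 with an estimated correlation), with 1 Leydig gene higher. Medians and means differed in sign for imprinted (0.32 and −0.03) and steroid genes (0.07 and −0.20), neither called. For Dnmt3a the value was 0.63 (adjusted p = 0.119). Calls of lists that ended with 1 library left out were undifferentiated spermatogonia without replicate 1 of WT at 19 dpp (camera adjusted p = 0.0619) and Leydig genes without replicate 2 of WT at 25 dpp (0.107). The Sertoli call ended without replicate 2 of KO at 19 dpp or replicate 1 of WT at 25 dpp (0.0597 and 0.0930). The piRNA call ended without replicate 2 of WT or replicate 1 of KO at 19 dpp (0.0865 and 0.0747), or without replicate 1 or 2 of WT or replicate 2 of KO at 25 dpp (0.0674, 0.09999 and 0.0604). Without replicate 2 of WT at 19 dpp pachytene, macrophage and red blood cell genes were called as lower (0.0136, 0.00230 and 0.0206). The latter pair was called as lower without replicate 2 of KO at 19 dpp too (0.0380 and 1.14e-05), macrophages without replicate 2 of KO at 25 dpp (0.0357), and methylation genes as higher without replicate 2 of WT at 25 dpp (0.0202). Calls numbered 2318 without replicate 1 of WT at 19 dpp, 1117 and 1755 without replicates 1 and 2 of KO at 19 dpp, 2428 without replicate 1 of WT at 25 dpp, and 1266 and 1833 without replicates 1 and 2 of KO at 25 dpp.

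X chromosome genes, which are silenced during meiosis in males, took 2.75 ± 0.251% of gene counts in WT and 3.77 ± 0.0630% in KO at 19 dpp, and 1.11 ± 0.124% in WT and 3.15 ± 0.133% in KO at 25 dpp. Of 729 X genes 147 rose and 8 fell at 19 dpp (144 and 8 adjusted over the list alone), with a median of 0.36. Adjusted p was 2.85e-06 by camera, and adjusted p = 0.840 with an estimated correlation. At 25 dpp 438 rose and 106 fell (448 and 111 adjusted over the list alone), with a median of 1.05 and a mean of −0.07. Adjusted p was 2.38e-11 by camera, and adjusted p = 0.840 with an estimated correlation. Among the X genes that fell were Akap4 (−11.02) and Tsga8 (−6.68). From 19 to 25 dpp in WT 116 X genes rose and 424 fell (116 and 433 adjusted over the list alone; median −0.91, mean 0.35; camera adjusted p = 6.31e-08, and adjusted p = 0.840 with an estimated correlation). In KO 38 rose and 89 fell (37 and 86 adjusted over the list alone), and the set was not called (camera adjusted p = 0.594). The log2 difference was higher at 25 dpp for 177 X genes and lower for 29 (220 and 35 adjusted over the list alone; median 0.51, mean −0.35, camera adjusted p = 3.70e-07, and adjusted p = 0.840 with an estimated correlation). Under Sertoli scaling the medians of KO over WT were −0.38 and −0.35 at the 2 ages. The 25 Y genes were not called as a set in any of the 5 contrasts (camera adjusted p between 0.594 and 0.890), but single Y genes changed in both directions. In KO against WT 3 rose and 1 fell at 19 dpp, and 10 rose and 12 fell at 25 dpp (median −0.0042, mean −3.66). From 19 to 25 dpp 12 rose and 5 fell in WT (median 0.10, mean 3.91), and 2 rose and 0 fell in KO. At 25 dpp 11 of the Y genes lacked counts in a group, so that the means depend on the prior count.

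Repeat families, counted in the deposited files beside the genes, were tested apart from them with 1065 families measured; this test and the families named were chosen after the values were seen. DNMT3A methylates transposons in male germ cells, and of these families 31 rose and 74 fell in KO at 19 dpp and 79 rose and 471 fell at 25 dpp. Under total counts 32 rose and 148 fell at 19 dpp and 242 rose and 270 fell at 25 dpp, and under Sertoli scaling 0 and 648, and 1 and 965, in edgeR. Repeat families took 5.47 ± 0.0558% of all counts in WT and 5.44 ± 0.334% in KO at 19 dpp, and 4.19 ± 0.134% in WT and 5.405 ± 0.156% in KO at 25 dpp. The retrovirus-like family MMVL30-int rose from 1267 ± 97.8 to 2713 ± 189 CPM at 19 dpp (1.10, SE 0.159, adjusted p = 0.00903) and from 809.5 ± 163 to 1994 ± 290.1 CPM at 25 dpp (1.30, SE 0.160, adjusted p = 5.12e-04), the latter −0.10 under Sertoli scaling. IAPEY4_I-int rose by 1.10 and 0.48 on the log2 scale, the latter −0.91 under Sertoli scaling, and MuLV-int by 0.81 and 1.30, which were −0.0525 and −0.0896 under Sertoli scaling. Of 25 IAP families, retrovirus-like elements too, 6 rose and 1 fell at 19 dpp and 8 rose and 5 fell at 25 dpp. A group of 25 LINE-1 families was picked by the name L1Md alone, whatever the age of the element. None rose in the edgeR test at 19 or 25 dpp (4 at 19 dpp and 0 at 25 dpp at an unadjusted p under 0.05), and 20 fell at 25 dpp. L1MdTf_III stood at 0.21 (adjusted p = 0.512) at 19 dpp and fell by 1.52 at 25 dpp, and in WT 23 L1Md families rose from 19 to 25 dpp.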

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

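All tests of the explanations in this part were chosen after the results were seen, except those of swapped labels (apart from its stromal comparison), of sequencing depth and of the Sertoli share, whose outcomes were written down first; when the Sertoli test counts as decisive was set later.

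The KO effect differed between the ages for 4464 genes, and the values that follow are log2 differences of the KO effect at 25 dpp minus that at 19 dpp. Among germ cell genes they were 1.71 for Spo11, 1.83 for Sycp2, 2.58 for Tex101, 1.02 for Foxo1, 2.76 for Stra8, 2.75 for Prdm9 and 1.97 for Tex15. They were −1.68 for Tbpl1, −7.82 for Catsper3, −4.75 for Tssk1, −5.00 for Tsga8, −2.76 for Odf2, −6.18 for Izumo1, −13.71 for Akap4, −9.29 for Spata20, −11.42 for Pmfbp1 and −1.33 for Tdrd7. Akap4, Pmfbp1, Catsper3 and Spata20 were near 0 counts at 19 dpp, so their values depend on the prior count. Cell cycle genes had 1.48 for Top2a, 1.71 for Mki67 and −1.84 for Plk1.

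Somatic and other genes had −1.48 for Tbc1d30, −0.80 for Scarb1, 2.55 for Gsta2, −1.02 for Col1a2, −1.79 for Col3a1, −1.41 for Col1a1 and 2.14 for Robo4. They had 5.24 for Galnt15, 3.99 for Gjc3, 3.71 for Atp8b4, 3.16 for Igfbp3, 2.95 for Ildr2, −1.03 for Mbd3, 1.30 for Igf2r and −3.11 for Fdft1. List medians were 0.75 for undifferentiated and 1.27 for differentiating spermatogonia, 2.03 for early meiotic prophase, −7.48 for round and −9.31 for elongating spermatids, 0.48 for Sertoli and −1.01 for Leydig cells. At 19 dpp 11 of 30 round and 8 of 23 elongating spermatid genes had no counts in at least 1 of the groups, so these medians depend on the prior count. Medians were 0.74 for the piRNA pathway and for p53 targets, 0.76 for the cell cycle and 0.51 for the X chromosome. With 1 library left out the camera call ended for undifferentiated spermatogonia (without replicate 1 of WT at 19 dpp, adjusted p = 0.0619) and for Leydig cells (without replicate 2 of WT at 25 dpp, 0.107). It ended for Sertoli cells without replicate 2 of KO at 19 dpp or replicate 1 of WT at 25 dpp (0.0597 and 0.0930), and for the piRNA pathway in 5 such settings (0.0604 to 0.09999).

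The KO libraries at 25 dpp lay closer to WT at 19 dpp (correlation across 23353 genes 0.974 to 0.989) than to WT at 25 dpp (0.764 to 0.87), where genes are not independent replicates. The 2 WT libraries at 19 dpp correlated with each other at 0.9856. Replicate 1 of them correlated with the KO libraries at 25 dpp at 0.9881 and 0.9894, and replicate 2 at 0.9743 and 0.9862. By this measure the 2 groups were thus about as close as the WT replicates at 19 dpp. Depth as the source of the gene differences between KO and WT at 25 dpp is argued against. With all libraries thinned to 22515812 gene counts 14016 genes still differed. Correlations were not computed on thinned counts, so for the closeness itself depth was not tested. Delay alone is argued against only in the strict form that puts every gene at a level between both WT ages. In KO at 25 dpp 13 genes lay above or below both, Col3a1 and Eln among the lower. WT was not measured between 19 and 25 dpp, and genes that dip or peak there could lie outside both under delay. The 13 genes thus do not argue against delay without that condition. For germ cell genes it stays open: 0 of 69 lay above both WT ages in edgeR, but against WT at 19 dpp only 2 genes of all rose (2898 changed at an unadjusted p under 0.05), and Tex15 and Prdm9 had means of 515 and 94.1 CPM, against 289 and 56.5 CPM in WT at 19 dpp and 215 and 22.3 CPM at 25 dpp. Swapped labels stay open. Between KO at 25 dpp and WT at 19 dpp 18 genes passed in edgeR, under the bound of 100 set beforehand. Of 12 stromal genes 9 were lower (median −0.78), where 8 of 12 were lower between the WT replicates (median −0.16, median size 0.30). Exchanging the labels of the 2 groups would leave that count and the size of each difference unchanged. These values therefore show how alike the groups are and cannot decide on a swap. By camera at the preset correlation stromal (adjusted p = 9.66e-12), peritubular myoid and steroid synthesis (6.33e-05 each), pachytene (0.00529) and piRNA genes (0.0328) were lower in KO. Sertoli (5.05e-09) and p53 target genes (0.0198) were higher, and the other lists were not called. With the correlation estimated no list was called (lowest adjusted p = 0.345).

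Steroid synthesis genes of Leydig cells were low in both KO libraries at 25 dpp and in replicate 1 of WT at 19 dpp. A set of 6, chosen after the values were seen and first drawn without Hsd17b3 (whose addition made both medians smaller in size), had a median of −2.852 for that WT replicate over the other and of −3.228 for KO over WT at 25 dpp, while all 19 Leydig genes had −0.80 and −0.74. Star was not low in KO at 25 dpp (16.6 and 18 CPM, against 10.2 and 56.9 in WT), and Hsd17b3 was 11.5 CPM in both WT replicates at 19 dpp. Less interstitial tissue as the whole cause for these 6 genes is argued against only as far as stromal and endothelial markers track that tissue. Their medians were −0.25 and 0.311 in the same comparisons. The second mixes opposite changes (quartiles −0.489 and 0.729), with Pdgfra and Dcn higher and Col3a1 lower in KO. Macrophage genes were lower in replicate 1 of WT at 19 dpp than in replicate 2 (geometric means 6.876 and 14.5 CPM). Red blood cell genes were lower there too, while peritubular myoid genes were not. For the smaller change of all 19 Leydig genes less interstitial tissue stays open. The 19 include Nr5a1, Gstm1 and Aldh1a1, which were higher in KO than in WT at 25 dpp. Their median of −0.74 in that comparison thus mixes opposite changes. Under Sertoli scaling (median of all genes moved by −1.41 at 25 dpp) the stromal and endothelial medians of KO over WT were −1.14 and −1.09. If the labels are right, the mutation cannot account for the WT replicate, but swapped labels were left open above. For the KO libraries the mutation cannot be told apart from variation between animals.

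Of the repeat families 18 rose in KO at both ages. Under Sertoli marker scaling 0 of these still rose at both ages in edgeR. That scaling moves the median of all genes by −0.82 and −1.41, more than most of these families rose, so its construction fixes this outcome and a larger share of Sertoli cell RNA in KO stays open. A rise of LINE-1 (L1Md) RNA through loss of DNMT3A stays open too. In edgeR 0 L1Md families rose at either age, and 20 of 25 fell at 25 dpp. At an unadjusted p under 0.05, 4 rose at 19 dpp and 0 at 25 dpp. The fall is confounded with the germ cell makeup, since in WT 23 of 25 L1Md families rose from 19 to 25 dpp and KO at 25 dpp was far lower than WT in spermatid genes.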

How the results depend on the processing

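The setting without replicate 1 of WT at both ages, limma-voom and DESeq2 without replicate 1 of KO at 19 dpp, and all settings of repeat families were added after the data were seen; the others were planned. With 1 library left out, counts ranged from 0 to 5632 for KO against WT at 19 dpp, 11219 to 15272 at 25 dpp, 10282 to 14361 for age in WT, 17 to 4794 for age in KO, 1117 to 5624 for the difference between the ages and 0 to 3709 for genes shared by both ages. The 0 came from edgeR without replicate 1 of KO at 19 dpp, with 5256 genes at an unadjusted p under 0.05, 0 by limma-voom and 3743 by DESeq2; fewer libraries leave 3 residual degrees of freedom. All settings with 1 library left out leave 3 residual degrees of freedom, so that alone does not account for the 0. Counts with a replicate block, 4508 and 14193 for KO against WT, stayed within 1.5 times the reported ones, and replicate differences of WT and KO correlated at 0.0483 and −0.0739 across genes at the 2 ages.

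Total count scaling gave 7517 genes (5548 higher and 1969 lower) for the difference between the ages and 180 repeat families at 19 dpp. Sertoli scaling gave 9921 genes at 19 dpp, 2661 for age in KO, 2757 for the difference between the ages, 8535 shared genes, and 648 and 966 repeat families. The Wald test gave 7830, 7318 and 7884 genes at 19 dpp, for age in KO and for the difference. The 2-fold test gave 517, 7553, 5725, 241 and 877 genes in the 5 contrasts and 391 shared, by its stricter question. Fitting only the groups compared gave 6698 genes for age in KO. With the correlation estimated, camera called 0, 0, 0, 0 and 0 lists in the 5 contrasts, where fry called 9, 9, 12, 7 and 2. The X median for age in KO was −0.25 with the 5 CPM filter, where the set was called. Apart from constructions named here, the cause was not tested.

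Values that turned under Sertoli scaling were, at 19 dpp, Etv5 −0.0902, Col1a2 −0.15, Mylk −0.28, Gnas −0.0317, MuLV-int −0.0525, L1MdTf_III −0.65 and ETnERV3-int −0.29. At 25 dpp they were Dnmt3a −1.11, Foxo1 −0.29, Tex15 −0.14, Tex101 −1.32, Gstm1 −0.34, Nr5a1 −0.56, Peg10 −0.19, Sesn1 −0.19, Top2a −1.29, Mki67 −0.70, MMVL30-int −0.10, MuLV-int −0.0896, RLTR6_Mm −0.10, IAPEY4_I-int −0.91 and ETnERV3-int −0.0881. The scaling itself shifts the median of all genes by −0.82 and −1.41. Without replicate 1 of WT at both ages the counts were 5796 at 19 dpp, 7756 for age in WT, 6210 for age in KO, 2116 for the difference between the ages and 4373 shared.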

Other observations

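Of the tests in this part, the contrast of KO at 25 dpp with WT at 19 dpp was added after the values were seen.

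In that contrast 2 genes rose, Atp8b4 and Cebpd, and 16 fell. The genes below both WT ages in KO at 25 dpp were Col3a1, Sned1, Alpl, Eln, Pcolce, Col5a3, Loxl1, Vill, Col6a2, Mfap4 and Fstl1. The difference between replicates 1 and 2 of WT at 19 dpp correlated with that of KO at 25 dpp at 0.361 across 23353 genes, and genes are not independent replicates.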
